A study of Homo sapiens with 4 samples.

How the data were processed

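Small RNA was measured in 4 libraries of human body fluid, 2 of CSF and 2 of serum, all from control donors. Per the labels' protocols, total RNA was extracted with a mirVana PARIS kit from 300 µl of CSF or 250 µl of serum, with 5 µl of a 5 nM synthetic worm miRNA (cel-miR-39) added as an extraction control and elution in 45 µl. Per the labels' protocols, the RNA was treated with T4 polynucleotide kinase, which leaves a 3' hydroxyl on fragments that lack one so that adapters can be ligated, and libraries were made with an NEBNext small RNA kit. This treatment raises the recovery of tRNA fragments relative to untreated RNA, so class shares apply to treated RNA. No molecular identifiers are named in the labels, so intervals and floors cover counting error only.

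The deposited values are whole-number counts per small RNA, 1 column per library. Bowtie2 2.4.1 and the genome build hg38 are named per the submitters' processing notes. Alignment settings, read filters, strand use and the handling of reads that match several entries are not given in the sources used here. Rows are named as miRNAs (2656), tRF5 (294), tRF3 (320), tRF1 (212), RNAs of a snoRNA track (402) and piRNAs (32046). Many piRNA names and tRNA fragments hold overlapping sequences, and copies of a tRNA are near identical, so single entries that share reads are uncertain. No row of the cel-miR-39 control was used here, and counts are therefore relative, not amounts per volume.

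Columns were matched to samples by the sample descriptions. The labels give the 2 libraries of each fluid as separate samples. Their counts differed by more than read sampling (chi-square 70447 on 678 degrees of freedom for CSF and 105418 on 635 for serum), so neither pair is 1 set of counts deposited 2 times; this does not show that the samples are separate. The Spearman correlation over features was 0.766 between the CSF libraries, 0.596 between the serum libraries and 0.208 to 0.402 between fluids, and features are not independent replicates. The top feature took 28.0%, 35.4%, 25.2% and 20.6% of the counts in CSF 1, CSF 2, serum 3 and serum 4, and the top 10 took 65.9%, 75.1%, 70.0% and 50.6%. A count of 0 allows up to 3 counts, or 10.0 to 18.2 CPM.

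Counts were normalized with TMM in edgeR 4.0.16 under R 4.3.3 (factors 1.03, 0.757, 1.01 and 1.27) and filtered with filterByExpr (minimum count 10). CSF was compared with serum by edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.859. Log2 fold changes are CSF minus serum, with a standard error approximated as the size of the change over the square root of the F statistic, and adjusted p values without a named tool come from this test. The median log2 fold change of the tested features was −0.41, so changes are relative to that scale. Both libraries of one fluid lay above both of the other in 54.6% of tested features, where chance gives 33.3%, and in 72 of the 74 calls. Features of the same libraries are not independent, so the excess over 33.3% is a description and not a test. Calls need a difference that is large against the spread within a fluid, so separation among them adds no support.

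tRNA fragments were also summed by anticodon and tested with the factors of the whole table; 78 fragment rows gave no usable anticodon. Class shares were compared with exact two-sided permutation tests and Wilson 95% intervals. Of 21 lists fixed before the data were examined, 11 had rows and 9 had at least 3 tested members, which camera and fry in limma 3.58.1 tested on voom values; mitochondrial tRNAs, Y, vault, ribosomal and spliceosomal RNAs and 5 mRNA lists were not analysed here. Folds against a fluid with no count use a floor of 3 counts over the group. DESeq2 1.42.0, limma-voom, other scalings, other filters and each library left out served as alternatives.

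Features were named by a rule written before the data were examined. It takes up to 10 features per direction with the largest change among calls with separated libraries and a mean of at least 100 CPM, the 5 most abundant per fluid, the 4 most abundant of each list, and up to 10 anticodons per direction.

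On 20 simulated tables of these 524 features with 200 changed, the test called 6.55% of features changed 4-fold and 48.5% of those changed 16-fold. It called 90.7% of those changed 64-fold, and 2.23% of its calls were false. Rises and falls were simulated in equal number, and the libraries of a fluid shared a mean. These rates therefore do not cover unequal directions of change or libraries of a fluid that differ as a block. Camera called a changed list in 20 of 20 tables and an unchanged list in 0. Every member of the changed list rose by 16-fold or more, and an unadjusted p under 0.05 counted as a call. These results therefore do not cover lists with smaller or mixed changes, or the adjusted p used for the real lists. The simulated features varied independently, so this does not cover lists whose members vary together. In these data the estimated correlation was 0.908 for the choroid plexus list and 0.667 for the brain list. Each estimate rests only on the differences between the 2 libraries of each fluid. Gene positions are from GENCODE 29 and a RefSeq gene table, both on GRCh38. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the remaining values. p values measure the spread between 2 libraries per fluid only.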

Results

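Small RNA was sequenced from cerebrospinal fluid (CSF), the fluid around the brain and spinal cord, and from blood serum of control donors. The series is about tRNA-derived fragments (tRFs), pieces cut from transfer RNAs, as possible diagnostic markers in these fluids. There were 4 libraries, CSF 1, CSF 2, serum 3 and serum 4, giving 2 per fluid. The samples of the fluids carry different numbers, which does not by itself show that the donors differ, and the fluids came from separate collections. Fluid therefore cannot be told apart from donor or collection in any comparison. The total count was 295932 in CSF 1, 290857 in CSF 2, 208300 in serum 3 and 135548 in serum 4. On the normalized scale 1 count was worth 3.34 CPM (counts-per-million) in CSF 1 and 6.07 in serum 4. Of 35930 rows (mature miRNAs, tRFs, snoRNA-track RNAs and entries named as piRNAs), 31475 held no count in any library and 524 were tested. A tRF5 entry is the 5' part of a mature tRNA, a tRF3 entry its 3' part, and a tRF1 entry the trailer removed from the precursor.

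The first comparison asked which RNA classes fill each fluid. 5' tRNA fragments took 55.4% ± 2.56 (SD, n = 2) of the counts in CSF and 27.3% ± 3.73 (n = 2) in serum. 3' tRNA fragments took 5.07% ± 1.32 in CSF and 0.727% ± 0.305 in serum (n = 2 each). Entries named as piRNAs, small RNAs best known from the germ line, held 31.4% ± 2.64 in CSF and 53.0% ± 14.5 in serum. The snoRNA-track RNAs, most of which guide chemical modification of ribosomal and other RNAs, held 1.76% ± 0.175 in CSF and 12.4% ± 12.9 in serum. Trailer fragments (tRF1) were rare in both fluids, at 0.0209% ± 0.00529 in CSF and 0.0570% ± 0.000228 in serum. The miRNA share was 6.32% ± 1.07 in CSF and 6.54% ± 4.98 in serum, with overlapping libraries.

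**Figure D1:**
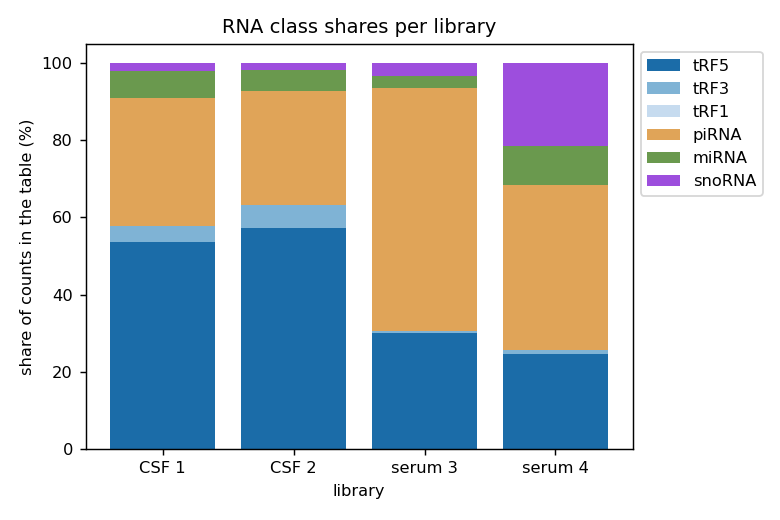
Share of each library's counts (vertical axis, percent) taken by each RNA class, 1 bar per library. The tRF5 share was 53.6% and 57.2% in the CSF libraries and 29.9% and 24.7% in the serum libraries, and the snoRNA share was 21.5% in serum 4.

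In the other 5 classes both libraries of one fluid lay above both of the other, which gives a two-sided exact permutation p of 0.333, the smallest that 2 against 2 allows; for miRNA the exact p was 1. The serum pair differed within itself: the snoRNA-track share was 3.29% (Wilson 95% interval 3.22 to 3.37) in serum 3 and 21.5% (21.3 to 21.8) in serum 4, and the miRNA share was 3.02% and 10.1%. The 10 features most abundant over all libraries together were then left out. Without them the difference between CSF and serum was 19.96 percentage points for tRF5 against 28.1 with them, and 0.820 against 4.34 for tRF3. The miRNA shares then no longer overlapped (19.7% and 21.3% in CSF, 7.93% and 16.3% in serum), and the piRNA shares did (53.0% and 46.95% in CSF, 79.4% and 46.87% in serum).

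The second comparison took the tRNA fragments by anticodon, summing all fragments of near-identical tRNA genes. Of 70 anticodon families, 39 were tested; 27 were higher in CSF and 0 in serum at a Benjamini-Hochberg adjusted p under 0.05 (edgeR quasi-likelihood). Fragments of Val-CAC, a valine tRNA, differed most, with 41406 ± 8990 CPM (SD, n = 2) in CSF against 157 ± 121 in serum (log2 fold change 8.04 ± 1.64 SE, adjusted p = 0.00103). The leucine tRNA families Leu-AAG (log2 fold change 6.42 ± 1.76) and Leu-TAG (5.28 ± 1.62) and the histidine family His-GTG (4.98 ± 1.64) followed, each in that direction in both CSF libraries. Glu-CTC fragments, the second most abundant in CSF, held 116105 ± 16155 CPM there against 9882 ± 9612 in serum (log2 fold change 3.55 ± 1.17, adjusted p = 0.0152).

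Other families higher in CSF were Ala-CGC (log2 fold change 4.41), Ala-TGC (4.24), Ser-TGA (4.11), Gly-TCC (4.08), Arg-CCG (3.90) and Asp-GTC (3.87), with adjusted p from edgeR between 0.00853 and 0.0271. The Asp-GTC counts rested largely on 1 library: its 3' fragments had 838 counts in CSF 1 and 12694 in CSF 2, and 2795 CPM in CSF 1 lay below 3320 CPM in serum 4. The most abundant family in both fluids did not pass: Gly-GCC fragments held 416817 ± 155963 CPM in CSF and 233206 ± 74608 in serum (log2 fold change 0.84 ± 0.79, adjusted p = 0.341). Lys-CTT (2.80 ± 1.43, edgeR adjusted p = 0.0821) and Gly-CCC (0.35 ± 1.35, adjusted p = 0.841) did not pass either. The Gly-CCC sum joins opposite directions. Its 3' fragments had 297 and 267 CPM in CSF against 1059 and 2616 in serum. Its 5' fragments had 3126 and 4873 CPM in CSF against 2339 and 710 in serum.

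**Figure D2:**
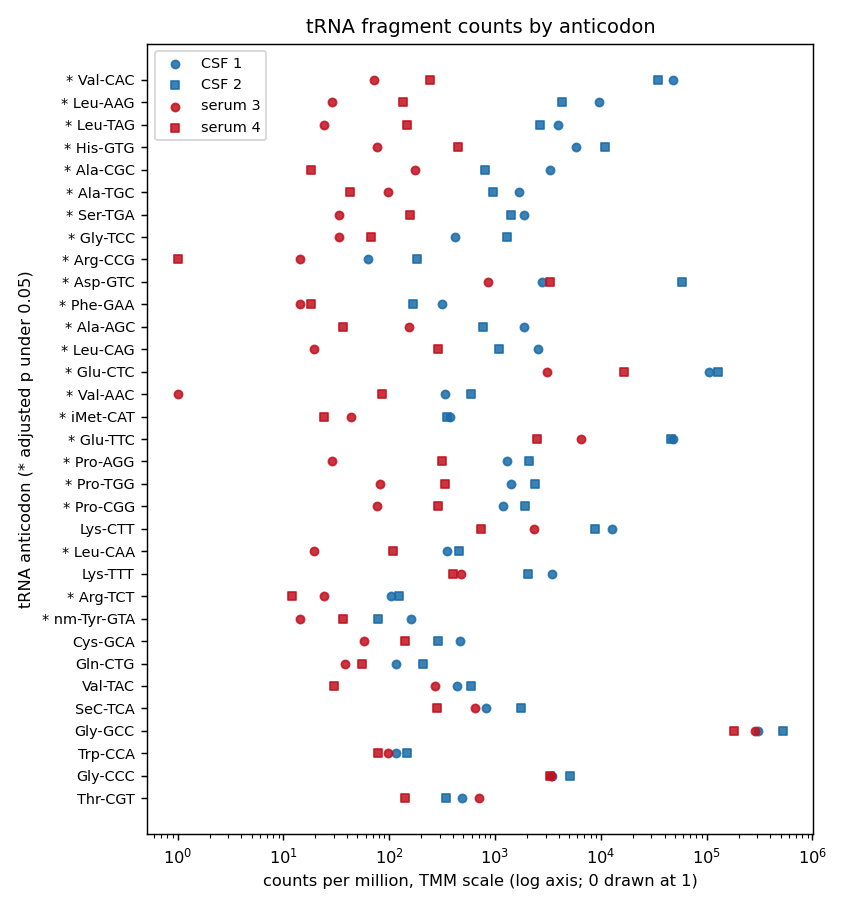
CPM on the TMM scale (horizontal log axis, 0 drawn at 1) of tRNA fragments summed by anticodon (vertical axis), 1 point per library, for families with a mean of at least 100 CPM in a fluid; a star marks an adjusted p under 0.05. Val-CAC stands farthest apart, with 41406 CPM in CSF against 157 in serum, while the Gly-GCC points lie close together.

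With total counts in place of the composition factors, 0 of the 39 families passed in edgeR, 18 had an unadjusted p under 0.05, and all named families kept their direction. With CSF 1 or CSF 2 left out, edgeR also called 0 families (6 and 11 at an unadjusted p under 0.05), while DESeq2 on all 4 libraries called 24 and limma-voom 23.

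The third comparison tested each small RNA on its own. It called 74 of 524 features: 61 were higher in CSF (14 tRF5, 8 tRF3, 8 miRNA and 31 piRNA-named entries) and 13 in serum (6 snoRNA-track, 3 miRNA and 4 piRNA-named entries), while 147 had an unadjusted p under 0.05. The abundant 5' fragment of Val-CAC listed as tRF5-Val-CAC-chr1-93 had 13372 and 7076 counts in CSF against 6 and 23 in serum (log2 fold change 8.84 ± 2.00, adjusted p = 0.00525). The lysine fragment tRF5-Lys-CTT-5-1 had 578 and 130 counts in CSF and 0 in both serum libraries. That is at least 170-fold higher in CSF against a floor of 3 counts over the serum group. Its entry is named for a tRNA gene on chromosome 16 (GRCh38, 3180554 to 3180626) that overlaps no annotated protein-coding or long non-coding gene. All 5' Lys-CTT fragments together had 3816 and 1875 counts in CSF and 485 and 114 in serum, so the family was not absent from serum. In serum, the leading entry was U71a, a guide RNA of the H/ACA type, with 19 and 108 counts against 2 and 0 in CSF.

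Among entries higher in CSF, piR-31103, piR-35412 and piR-35410 were also at 0 in serum, at least 166-fold, 158-fold and 152-fold higher. Their counts lay close to those of tRF5-Lys-CTT-5-1 in both CSF libraries (560, 514 and 528 against 578 in CSF 1), so whether they are separate RNAs is uncertain. A second lysine entry, tRF5-Lys-CTT-14-1, named for a locus that RefSeq lists as a pseudogene, was at least 70.6-fold higher. The entries piR-36706 and piR-57234 were at least 29.5-fold and 27.1-fold higher. The 3' fragment tRF3-Glu-TTC-2-2 is named for a tRNA gene on chromosome 15 (26082234 to 26082305). It had 10004 and 3287 counts in CSF against 225 and 49 in serum (log2 fold change 5.13 ± 1.76, edgeR adjusted p = 0.0364). This entry was picked after its values were seen.

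The serum calls included 6 snoRNA-track entries, of which 0 passed when adjusted over the 106 tested entries of that track alone. Serum 4 weighed most: its share lay above both CSF libraries for 104 of 105 entries with at least 50 counts, against 60 of 105 for serum 3, and it also had the most miR-451a, an erythroid miRNA (4722 CPM against 399.5 in serum 3). U3, the box C/D RNA needed to process the ribosomal RNA precursor, had 105 and 2267 counts in serum against 39 and 36 in CSF (log2 fold change −5.59 ± 1.98, adjusted p = 0.0417). ACA53 (log2 fold change −6.03 ± 2.09), ACA43 (−4.86 ± 1.78), U70 (−4.75 ± 1.45) and U17b (−4.60 ± 1.63) were also higher in serum in both libraries. ACA53 is SNORA53, on chromosome 12 (98599635 to 98599883), and overlaps an annotated exon of SLC25A3. U70 is SNORA70, on chromosome X (154400281 to 154400415), and overlaps an annotated exon of the ribosomal protein gene RPL10. Overlap by any base with an exon of any annotated transcript was counted, so both may still lie in introns of other transcripts. The other serum entries named by the rule were piR-31703 (log2 fold change −6.21 ± 1.91), piR-44591 (−5.11 ± 1.59) and miR-10396b-5p (−3.65 ± 1.35).

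Of the features named for their abundance, tRF5-Val-CAC-chr1-93 alone passed the test. tRF5-Gly-GCC-3-1 alone took 31.7% ± 5.28 of the counts in CSF and 22.9% ± 3.24 in serum (n = 2 each; log2 fold change 0.83 ± 1.04, adjusted p = 0.628). It is named for a tRNA gene on chromosome 16 (70778211 to 70778281) inside an intron of VAC14. tRF5-Gly-GCC-1-5 (log2 fold change 0.86 ± 1.36, adjusted p = 0.692) and piR-31038 (0.28 ± 1.19, adjusted p = 0.889) did not pass. piR-35982 and piR-31068, with nearly equal counts in each library, held 6.90% ± 5.53 and 6.90% ± 5.43 in serum against 2.37% ± 0.170 and 2.38% ± 0.178 in CSF, and did not pass (adjusted p = 0.543 for both). tRF5-Glu-CTC-2-1 took 10.05% ± 0.780 in CSF against 1.17% ± 1.21 in serum (log2 fold change 3.55 ± 1.38, adjusted p = 0.0632), and piR-38736 0.124% ± 0.0934 against 2.80% ± 3.35 (adjusted p = 0.0770).

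The 74 calls fell to 0 in edgeR when CSF 1 or CSF 2 was left out (57 and 39 features at an unadjusted p under 0.05), where the spread rests on the serum pair, and were 135 and 113 without serum 3 or serum 4. They were 130 with DESeq2, 18 without a filter on low counts, and, with the piRNA-named rows left out, 22 against 39 calls among the same kinds of rows.

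The fourth comparison used feature lists fixed before the data were examined. Of the choroid plexus miRNAs, named for the tissue that secretes CSF, all 3 tested members rose in CSF (3 also when adjusted over the list alone), 2 of them arms of the miR-204 hairpin. The list was called by camera with its preset correlation (adjusted p = 0.00461), but not with an estimated correlation (adjusted p = 0.794) or by fry (adjusted p = 0.173). miR-204-5p had 42 and 135 counts in CSF and 0 in serum, at least 42.5-fold higher; its gene lies on chromosome 9 (70809975 to 70810084) in an intron of TRPM3. miR-34c-5p, abundant in ciliated epithelium, had 25 and 107 counts against 0, at least 31.7-fold higher. miR-204-3p had 99 counts in CSF against 1 in serum, a ratio of 71.4 (95% counting interval 12.5 to 2846). The median log2 fold change of the list was 9.001, or 5.41 with members absent from serum set at their bound. miR-1298-5p, below the filter, had 10 and 30 counts in CSF and 0 in serum.

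Of 8 tested brain miRNAs, 2 rose in CSF, and 2 when adjusted over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.794 with an estimated correlation). These were the neural miRNAs miR-9-3p, with 29 and 20 counts against 0 in serum (at least 11.8-fold higher), and miR-9-5p, with 29 counts against 1 (ratio 20.9, 95% counting interval 3.47 to 854). The most abundant members did not pass: miR-99a-5p held 18032 ± 17806 CPM in CSF and 1966 ± 2079 in serum (adjusted p = 0.182), and miR-125b-5p 1364 ± 1296 against 83.6 ± 70.6 (adjusted p = 0.138). miR-29a-3p and miR-100-5p had adjusted p values of 0.459 and 0.543. miR-128-3p was the only tested member with a fitted value higher in serum. It had 56.7 and 175 CPM in CSF against 19.3 and 425 in serum (log2 fold change −0.94 ± 1.47, edgeR adjusted p = 0.692).

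**Figure D3:**
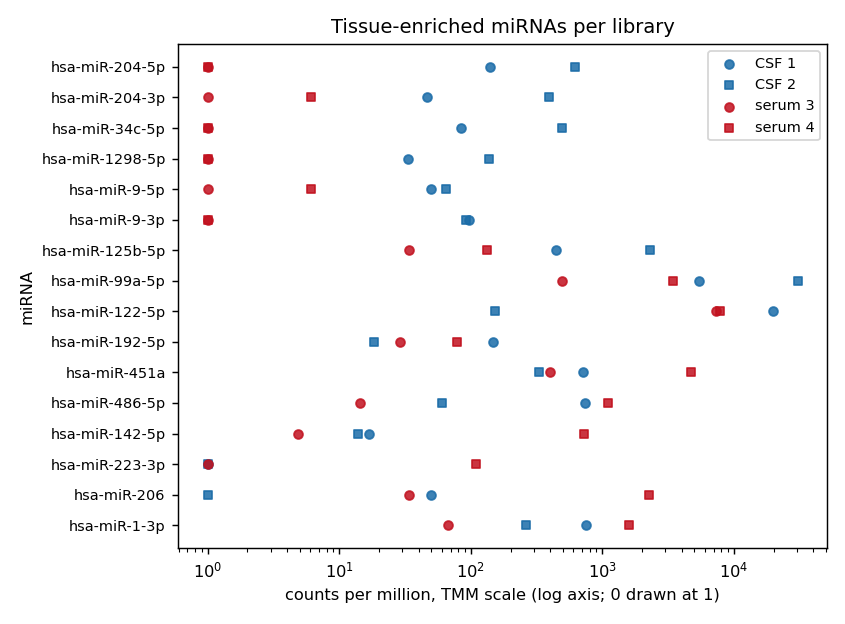
CPM on the TMM scale (horizontal log axis, 0 drawn at 1) of miRNAs from the fixed lists (vertical axis), 1 point per library. miR-204-5p, miR-34c-5p and miR-9-3p had 0 counts in both serum libraries, and miR-122-5p was at 19751 CPM in CSF 1 against 152 in CSF 2.

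Of 77 tested fragments of nuclear tRNAs, 20 rose in CSF and 0 in serum; adjusted over the list alone the counts were 41 and 1, the 1 being tRF3-Gly-CCC-6-1 (log2 fold change −4.86 ± 1.97). The camera adjusted p of this list was 7.84e-17, and adjusted p = 0.0680 with an estimated correlation. That estimate was −0.0028, below the preset 0.01, so a higher correlation between fragments does not account for the weaker result. The setting with an estimated correlation thus changes more than the correlation. The weaker results of the choroid plexus and brain lists under it cannot be put down to correlated members alone. Blood-related lists gave no call and large differences between libraries. None of 5 tested red cell miRNAs passed, before or after adjustment over the list alone (0 each): miR-451a had 710.5 and 327 CPM in CSF and 399.5 and 4722 in serum (log2 fold change −2.30 ± 1.75, adjusted p = 0.406), and miR-486-5p, miR-92a-3p and miR-25-3p had adjusted p values of 0.861, 0.889 and 0.367. The 5 tested platelet and endothelial miRNAs gave 0 calls (0 adjusted over the list alone), with miR-191-5p at 60.1 ± 32.9 CPM in CSF and 334 ± 404 in serum. The 4 tested liver miRNAs gave 0 calls (0 adjusted over the list alone); miR-122-5p, the main liver miRNA, had 5921 and 33 counts in CSF and 1505 and 1291 in serum (log2 fold change 0.40 ± 1.53, adjusted p = 0.881). The 7 tested let-7 miRNAs gave 0 calls (0 adjusted over the list alone), with let-7b-5p at 2448 ± 2453 CPM in CSF and 337 ± 218 in serum (adjusted p = 0.284). In the muscle list miR-206 was higher in serum (15 and 0 counts in CSF, 7 and 372 in serum; adjusted p = 0.0497; 1 call adjusted over the list alone), which rested on serum 4. Of the white blood cell miRNAs, 2 were tested and 0 passed (0 adjusted over the list alone), and miR-142-5p had 119 of its 120 serum counts in serum 4.

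The piRNA-named list held 31 entries higher in CSF and 4 in serum among 248 tested (31 and 4 adjusted over the list alone); its median log2 fold change was −0.58, its mean 0.18, and camera put it lower in CSF where fry put it higher (adjusted p = 0.387 and 0.728). Of 4 tested entries named SNORD or SNORA, 0 passed (0 adjusted over the list alone), SNORD119 having a log2 fold change of −3.23 ± 1.81 (adjusted p = 0.230).

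By camera with a preset correlation of 0.01, 3 of 9 lists were called: nuclear tRNAs, choroid plexus miRNAs and brain miRNAs. With an estimated correlation 0 of the 3 held, at the p values given above, and fry called the nuclear tRNAs (adjusted p = 0.0159).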

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

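No paired analysis was possible because the CSF and serum libraries share no replicate number. Scaling by the spike-in, leaving out ribosomal RNA and other pseudocounts were not run: no such rows were used, and the values are counts. Leaving out the piRNA-named rows was chosen after seeing the data. Calls rest on 2 libraries per fluid: leaving 1 out took the number of called features from 0 to 135 (0 to 86 higher in CSF, 0 to 53 higher in serum), of anticodons from 0 to 29 and of lists from 1 to 3, and a lone library is then assumed to vary like the other pair. Features called numbered 130 with DESeq2 (102 higher in CSF, 28 in serum, 67 shared with the 74), 18 without a filter (18 and 0; 17 shared, more features being tested) and 22 without piRNA-named rows (21 and 1). The 13 features higher in serum were 8 with DESeq2 size factors, 8 without the 10 most abundant features in the library sizes, 8 with limma-voom, 20 with at least 10 counts per library and 7 with copies summed. Anticodons called numbered 0 with total counts alone, and 23 to 32 in the other settings with all libraries. Lists called numbered 0 with an estimated correlation and 1 with fry. Without the 10 most abundant features, the CSF minus serum share was 19.96 points for tRF5, 0.820 for tRF3, −0.0537 for tRF1 and 8.40 for miRNA, whose libraries then separated while those of piRNA overlapped. The median over features of the shift in log2 fold change was 0.25 with DESeq2 size factors, −0.36 with total counts and 0.32 with the top 10 left out. Where not stated, the cause was not tested.

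No named feature among the calls changed direction; these uncalled log2 fold changes did. miR-24-3p was 0.0399 with DESeq2 size factors, 0.0629 with the top 10 left out, 0.0406 with DESeq2, 0.38 without a filter and 0.24 without piRNA-named rows. SNORA38B was 0.38, 0.36, 0.40, 0.62 and 0.46 in those settings, and 0.10 with copies summed. With total counts piR-31038 was −0.071 and let-7a-5p −0.42, the latter also −0.0372 with at least 10 counts per library. With limma-voom miR-486-5p was 0.63, miR-122-5p −2.09 and miR-1-3p 0.42. miR-486-5p was 0.59 and miR-1-3p 0.31 without a filter, and 0.83 and 0.49 without piRNA-named rows. Leaving out 1 library gave ranges of −0.44 to 3.25 for miR-92a-3p, −1.92 to 0.33 for miR-151a-3p, −0.37 to 0.49 for miR-24-3p, −5.35 to 1.71 for miR-122-5p, −1.06 to 1.86 for miR-192-5p, −1.53 to 1.23 for SNORA38B, −2.45 to 4.75 for miR-486-5p, −1.11 to 2.90 for miR-1-3p, −2.01 to 0.67 for piR-35982, −1.997 to 0.64 for piR-31068, −0.26 to 2.85 for let-7a-5p, −0.17 to 1.38 for piR-31038, −2.64 to 0.37 for miR-451a, −2.57 to 0.59 for miR-25-3p, −2.80 to 0.33 for miR-191-5p, −2.03 to 2.05 for miR-126-3p and −1.22 to 0.0727 for SNORD126. Lists whose direction turned had adjusted p values of 0.146 to 0.897 (red cell), 0.279 to 0.897 (liver), 4.82e-06 to 0.553 (piRNA) and 0.101 to 0.989 (let-7) with 1 library left out, and 0.728 by fry for piRNA. At these depths a 4-fold change was called in 6.55% of simulated cases.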

Other observations

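The snoRNA-track RNAs were compared as a list added after the names were seen. Of 106 tested entries, 103 had a fitted value higher in serum, 6 passed the test there and 0 in CSF; adjusted over the list alone 0 passed. The direction rested largely on serum 4, whose share lay above both CSF libraries for 104 of 105 entries with at least 50 counts, against 60 of 105 for serum 3. Camera with its preset correlation gave p = 3.42e-11, and p = 0.356 with an estimated correlation. U63, the most abundant in serum, held 14608 ± 5949 CPM in serum and 1347 ± 669 in CSF (SD, n = 2 each; log2 fold change −3.44 ± 1.69, edgeR adjusted p = 0.156). Beyond the fixed lists, miR-4443 was higher in CSF, with 612 counts against 2 in serum (ratio 221, 95% counting interval 60.8 to 1825, edgeR adjusted p = 0.0162). The entry miR-203a-3p was at least 23.8-fold higher, with 53 and 46 counts against 0. Its opposite-strand partner miR-203b-5p had nearly equal counts (59 and 47 against 0), so which of them the reads came from is uncertain.

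The weighing tests that follow were chosen after the result was seen, except that of abundant features; the edgeR test above was planned, and miR-4443, miR-203a-3p and U63 were picked after their values were seen. No biological explanation was tested, since the design names no group within a fluid.

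The liver miRNA miR-122-5p held 2.00% of the counts in CSF 1 (Wilson 95% interval 1.95 to 2.05) and 0.0113% in CSF 2. Serum like that of the serum libraries mixed into the sample is argued against, since the share in CSF 1 was 2.10 times (exact 95% interval 1.98 to 2.23) that of the higher serum library. The entry miR-122b-3p followed miR-122-5p, with 4487 and 28 counts in CSF and 1175 and 1258 in serum. Its share was 1.52% in CSF 1 and 0.928% in serum 4. Which entry the reads came from is uncertain, and the interval does not cover how reads were split. The red cell miRNAs were higher in CSF 1 than in CSF 2 by a median log2 ratio of 2.17 over 9 members. They lay at the 99.99 percentile of 10000 random miRNA lists matched on mean. Of 13 listed members, 5 also had at least 10 counts in CSF 2. Random lists hold miRNAs drawn singly, while the red cell list had an estimated correlation of 0.967 over 5 tested members. That estimate comes from the differences within the 2 pairs of libraries, CSF 1 against CSF 2 among them. It is therefore not separate evidence that the members vary together. Where members do vary together, the percentile overstates how far the list stands out, and by how much was not tested. Blood in the sample may contribute. It leaves much open, because miR-451a was 710.5 CPM in CSF 1 against 327 in CSF 2 while miR-122-5p was 19751 against 152, the white cell and platelet lists lay at the 29.8 and 34.2 percentiles, the liver list, which holds miR-122-5p, at the 99.96 percentile and the choroid plexus list at the 0.56 percentile. Serum of this donor with more miR-122-5p than the 2 serum libraries was not tested.

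The snoRNA-track share was 21.5% in serum 4 and 3.29% in serum 3. A few abundant features setting the totals is argued against as the whole cause. Without the 10 features most abundant over all libraries together, the share was 34.8% in serum 4 and 8.64% in serum 3, still 4.02 times. These 10 were picked on counts that include CSF, so they are not the 10 largest of each serum library. A partial contribution of abundant features stays open. Blood cell RNA in serum 4 may contribute. miR-451a was at 4722 CPM there against 399.5 in serum 3. For the ratio of serum 4 to serum 3, the red and white cell miRNAs, with 15 members, lay at the 99.17 percentile of random lists. Members that vary together limit this percentile as well. For the same ratio the platelet and endothelial list lay at the 31.1 percentile and the muscle list, with 3 members, at the 94.96 percentile. How serum 4 was collected was not tested.

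Several entries had nearly equal counts, such as piR-35982 and piR-31068 (7374 and 7418 in CSF 1, 22512 and 22360 in serum 3). Counting whatever the strand is a candidate explanation for some: in 100% of the 6 miRNA pairs from genes that overlap on opposite strands, the minor entry had at least 10% of the counts of the major one, as with miR-423-5p (738) and miR-3184-3p (714). Whether reads matching several entries were given to 1 of them at random could not be decided. Of 732 entry pairs even in CSF, 5.74% were even in serum, but on a simulated table that held 100 such shared pairs the same rule gave 12.1%, because pairs equal by chance outnumber shared ones. The low value is therefore no evidence against random assignment.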
